A study of Caenorhabditis elegans with 14 samples.

How the data were processed

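Small RNA libraries of young adult C. elegans were compared. Per the labels' protocols, animals were synchronized by timed egg laying, total RNA was extracted with Trizol and chloroform and treated with DNaseI, and libraries were made with an Apollo instrument and a small RNA kit, 12 PCR cycles and size selection on a Pippin instrument. The 12 libraries analysed are described in the labels as 5'-independent, and their extraction protocol includes a polyphosphatase step, which makes RNAs with a triphosphate at their 5' end available for ligation. A further 2 libraries of strain HC125, described as 5'-dependent, had no column that could be assigned to them, and the comparison of both library types is not analysed here.

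The authors deposited 1 table of raw read counts per gene, with 1 column per library, made from reads of 21 to 26 nt per the name of the table. Per the submitters' processing notes Bowtie2 and HTSeq were used. Their versions, the genome build, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The counts are whole numbers, and their totals differ between libraries, as in a table that is not normalized. A total is therefore the number of 21 to 26 nt reads assigned to genes, not the sequencing depth of the library, which is not given in the sources used here. Gene names, biotypes and coordinates were taken from the Ensembl release 115 annotation of build WBcel235 by gene ID, which need not be the build behind the counts: 20194 of the 20541 IDs were in it and 347 were not. Small RNAs against a gene here means reads counted at that gene. Since the strand setting is not given, reads of its sense strand may be included. A count does not measure its messenger RNA.

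Everything that follows was computed from those counts in R 4.3.3. A single model was fitted to the 12 libraries in 5 groups, so that groups of 2 shared 1 estimate of the spread, with 7 residual degrees of freedom. That estimate need not hold in each group. Replicates correlated on log CPM at 0.887 in N2, 0.905 to 0.976 in HC125 and 0.981 in hrde-1;HC125. They correlated at 0.984 at F6 and 0.944 at F21, though shallow libraries also vary more by counting error. A shared spread may therefore be too small for some comparisons and too large for others. edgeR 4.0.16 was used with filterByExpr (minimum count 10, minimum total count 15), TMM scaling and the robust quasi-likelihood F test (two-sided). A gene was called where its Benjamini-Hochberg adjusted p over all 10470 tested genes lay under 0.05. CPM values are counts per 1e+06 counts of a library, scaled by the TMM factors, given as mean ± SD over libraries. Standard errors (SE) of log2 fold changes were derived from the F statistic. The p-values measure only the spread between these samples, since the labels do not say whether replicates were separate cultures.

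The named genes followed a fixed rule. sid-1, hrde-1 and the 3 annotated genes on each side of sid-1 were always reported. In each comparison, up to 8 called genes with the largest rise and up to 8 with the largest fall were named, where every library of one group lay above every library of the other and the higher group had a mean of at least 10 CPM. Up to 4 members of each gene list with the smallest adjusted p were named, with fewer where a list had no called member. The 10 genes with the highest mean CPM were named for library composition.

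The 16 gene lists were systemic RNAi, small RNA pathway, ERGO-1-class 26G siRNA targets, nuclear RNAi and WAGO-class targets, spermatogenesis genes, major sperm protein genes, germline and oocyte genes, muscle genes, intestine genes, hypodermis and cuticle genes, neuron genes, transformation marker genes, histone genes, microRNAs, 21U-RNAs and the sid-1 neighbourhood. Their members came from general knowledge of the field, or for the last from the annotation. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The design, the named gene rule, the lists and the alternatives were fixed before the data were examined, apart from the alternatives said to be chosen after seeing the data. sid-1 belongs to both the systemic RNAi list and the sid-1 neighbourhood, and unc-54 to both the muscle and transformation marker lists.

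For a group with 0 counts of a gene, a fold is given as a lower bound, with a floor of 3 counts summed over the group. For 1 to 3 counts, the ratio has a 95% counting interval (exact Poisson test of 2 rates). PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. In the shallowest library 3 counts came to 6.65 CPM, and in the deepest to 0.47 CPM.

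The test was tried on simulated data: negative binomial counts drawn from each gene's mean over all libraries, its fitted dispersion and the real library sizes. In each comparison 100 genes of at least 10 CPM were changed 2-fold and 100 were changed 4-fold. Of the 2-fold and 4-fold genes respectively, it recovered 53% and 92% for HC125 against N2 (10058 genes tested), 65% and 98% for hrde-1;HC125 against HC125 (10062 genes), and 44% and 87% for hrde-1;HC125 against N2 (10053 genes). For the non-array groups it recovered 32% and 89% for F6 against F21 (10077 genes), 30% and 84% for F6 against N2 (10067 genes), and 34% and 80% for F21 against N2 (10055 genes). False calls made up 4.73% to 7.69% of calls over these simulations. A simulated set of 40 genes changed 2-fold was found in all 6 comparisons. Genes were drawn independently, with the same spread in every group, so correlated lists and unequal spread were not tried. In the real data the estimated correlation was 0.834 for major sperm protein genes in HC125 against N2.

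The alternatives were median-of-ratios scaling, library size without TMM, no low-count filter, a filter of 10 CPM in 2 libraries, the replicate number as a block, DESeq2 1.42.0, a fit of only the 2 groups compared, each library left out in turn, camera with an estimated correlation, and fry. Among genes with at least 100 counts, 52 of 9240 had counts identical to those of another gene in every library, in 26 sets. Such genes share their reads with a copy, so their values are uncertain.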

Results

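Small RNAs of 21 to 26 nt were counted per gene in 12 libraries from young adult C. elegans in 5 groups. The series concerns heritable silencing at an endogenous gene. The groups were wild type N2 (n = 2), strain HC125 with Psid-1::gfp, a gfp gene under the sid-1 promoter (n = 4), hrde-1;HC125, the same with a mutated hrde-1 (n = 2), and the strain HC83 lines labelled non-array, silenced at generation F6 (n = 2) and de-silenced at F21 (n = 2). sid-1 encodes a double-stranded RNA channel needed for systemic RNAi, and hrde-1 encodes a nuclear Argonaute of the germline that carries heritable silencing. By contrast with the non-array lines, HC125 and hrde-1;HC125 are called the array groups. The reads assigned to genes numbered 470115 and 847628 in N2, 451389, 1095472, 1811918 and 3741687 in HC125, and 6379388 and 3881568 in hrde-1;HC125. They numbered 3203182 and 3716646 at F6, and 3758704 and 514814 at F21, a 14.1-fold range over all libraries. Of 20541 genes, 18202 had a count and 10470 were tested.

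Small RNAs against sid-1 (WBGene00004795, WBcel235 V:5119970-5126916, plus strand) were most at F6, next in HC125 and fewest in hrde-1;HC125, and N2 and F21 did not differ (adjusted p = 0.846). They came to 836 and 786 CPM in N2, 2542, 2398, 2031 and 2279 in HC125, 557 and 506 in hrde-1;HC125, 4732 and 4159 at F6, and 731 and 801 at F21. Small RNAs against hrde-1 (WBGene00007624, III:4172337-4176159, minus strand) came to 861 and 816 CPM in N2, 841, 839, 1273 and 1096 in HC125, and 471 and 540.3 in hrde-1;HC125. They came to 982 and 1016 CPM at F6 and 989 and 966 at F21. These are small RNAs counted at the gene, and they measure neither its messenger RNA nor the mutation.

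**Figure D1:**
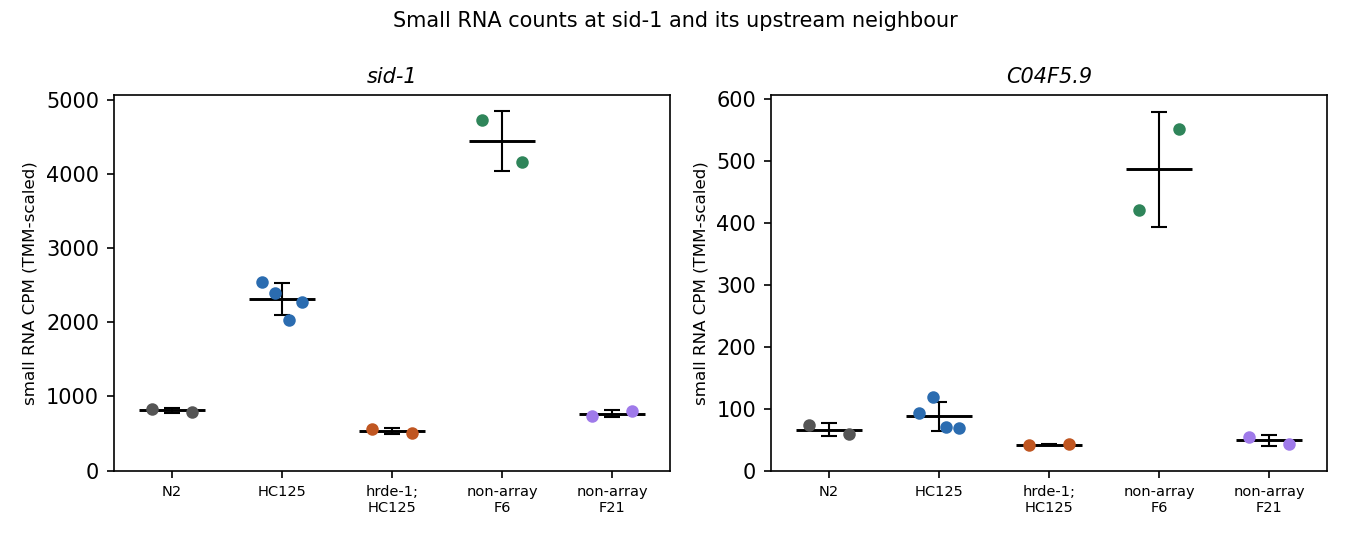
Scaled counts (CPM) of small RNAs against sid-1 and its neighbour C04F5.9 in each of the 12 libraries, with the group mean as a line and the SD as a bar. The F6 libraries had 4732 and 4159 CPM at sid-1, above the 4 HC125 libraries at 2031 to 2542 CPM.

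The gene next to sid-1, C04F5.9 (WBGene00015451, V:5114715-5119209, minus strand), had 486 ± 93.2 CPM (SD, n = 2) at F6, against 65.8 ± 10.5 in N2 (n = 2), 87.5 ± 23.5 in HC125 (n = 4), 41.6 ± 1.00 in hrde-1;HC125 (n = 2) and 48.8 ± 8.55 at F21 (n = 2). The next gene, C04F5.8 (WBGene00015450, V:5111518-5113754), had 25.99 ± 4.04 CPM in hrde-1;HC125 and 8.37 ± 2.05 in HC125. ugt-63 (WBGene00015449) and F14F9.4 (WBGene00017467) lay near the floor, with at most 16 and 46 counts per library, and were not called in any comparison. F14F9.5 and F14F9.8 had too few counts to be tested.

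The pseudogene Y52B11A.18 (WBGene00206497, I:11059299-11061435) had the most small RNAs in every library, with 14610 ± 4020 CPM in N2, 14067 ± 6796 in HC125, 46639 ± 3753 in hrde-1;HC125, 17414 ± 306.9 at F6 and 15271 ± 420.6 at F21. It rose in hrde-1;HC125 against HC125 by 1.73 ± 0.37 on the log2 scale (SE, adjusted p = 0.0105). By the mean over all 12 libraries, to which hrde-1;HC125 added most for some, next came W09C5.12, B0250.8, the noncoding RNA gene C47G2.8, the pseudogene F37H8.2, bath-45, zip-2, got-1.2, sqst-1 and eri-6, in an order that differed between groups. B0250.8 had 14251 ± 918 CPM in hrde-1;HC125 and 4339 ± 906 in HC125. By gene class 89.9% of the counts fell on protein-coding genes and 7.79% on pseudogenes. The first principal component (30.5% of the variance) set the hrde-1;HC125 libraries apart. N2 replicate 2 and HC125 replicates 1 and 2 stood apart on the second (24.8%), at -63.7, -49.7 and -37.9. On the third (11.4%) N2 replicate 1 stood apart at 68.5, with F21 replicate 2 at -32.6.

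HC125 was compared with N2 to ask which small RNAs accompany the Psid-1::gfp array (n = 4 and 2). At sid-1 small RNAs rose 2.85-fold, a log2 fold change of 1.51 ± 0.14 (SE, adjusted p = 9.62e-06), and were higher in 4 of 4 HC125 libraries than in either N2 library. The make-up of the array is not given in the sources used here, and counts per gene hold no positions. Small RNAs against any sid-1 sequence on the array may therefore be counted here. Those counted at aex-5 (WBGene00000088, I:14850052-14855827), which encodes a protease of the prohormone convertase type, came to 1056 ± 102 CPM against 1.12 ± 1.59 in N2. With 2 counts in N2, the ratio was 672 (95% counting interval 186.0 to 5552, adjusted p = 5.20e-11). At the adjacent gene unc-54 (WBGene00006789, I:14855901-14863482), the major myosin heavy chain of body wall muscle, they rose by 4.97 ± 0.42 (adjusted p = 0.00016), from 26.9 ± 19.2 to 946 ± 77.9 CPM. Those against prx-11 (WBGene00004196, I:12971615-12972259), a gene of peroxisomes, fell by 3.16 ± 0.25 (adjusted p = 6.72e-06), from 275 ± 3.08 to 30.7 ± 11.5 CPM.

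**Figure D2:**
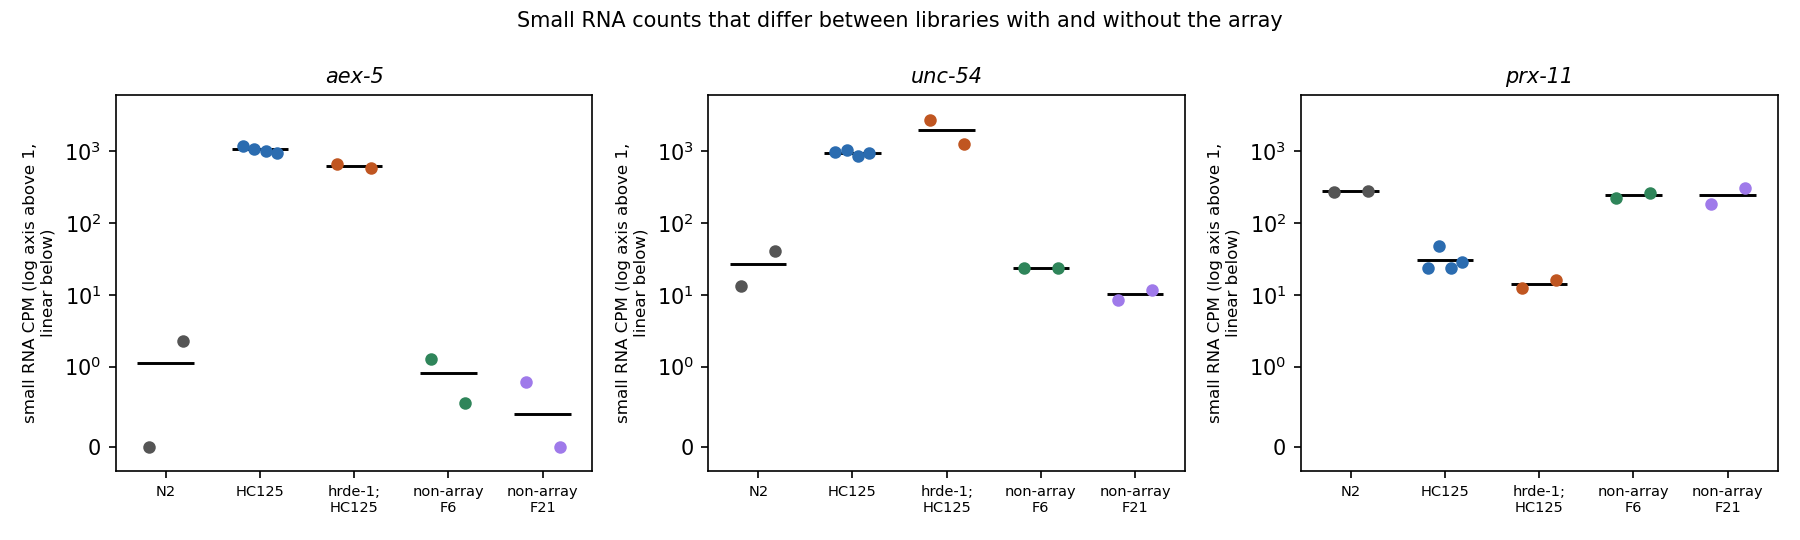
Scaled counts (CPM, log axis above 1 and linear below) of small RNAs counted at aex-5, unc-54 and prx-11 in each library, with the group mean as a line. The 6 array libraries had 576 to 1187 CPM at aex-5 against at most 2.25 in the 6 others, 843 to 2705 at unc-54 against at most 40.4, and 12.4 to 47.5 at prx-11 against at least 183.

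In this comparison 53 genes were called, 23 higher and 30 lower, and 1101 had an unadjusted p under 0.05. Both copies of srd-71 (WBGene00005148 and WBGene00021572), a chemoreceptor gene, share their counts and rose by 4.43 ± 0.36 (adjusted p = 2.22e-06). Higher too were the 2 copies of clec-209 (WBGene00018910 and WBGene00021224, 5.30, identical counts), the spermidine synthase gene spds-1 (3.24) and mct-2 (WBGene00015273, 3.11), which has the same values as its copy WBGene00021227. Along with srd-73 and F56A4.12, named in other comparisons, srd-71, clec-209 and mct-2 lie in a segment of chromosome V that has a second copy beside it. The falls included fbxa-216 (-2.38), R03D7.2 (-2.08), pqn-52 (-2.04), suca-1 (-2.01), sor-3 (-1.64), the titin-like gene ttn-1 (-1.62) and ttm-1 (-1.41). The transformation marker gene lin-15B fell by 0.70 (adjusted p = 0.0485).

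Of the 17 named genes called beside sid-1 in HC125 against N2, 7 kept their call under every omission of 1 library. Without N2 replicate 1, the calls of clec-209 (5.34), spds-1 (3.65), mct-2 (2.76), fbxa-216 (-2.09), sor-3 (-1.58), ttn-1 (-1.42), ttm-1 (-1.23) and lin-15B (-0.81) ended, R03D7.2 was at -1.26 and aex-5, with 2 counts in N2, had a ratio of 432 (interval 119.7 to 3571). Without N2 replicate 2, those of clec-209 (5.23), spds-1 (2.70), mct-2 (3.85), fbxa-216 (-2.65), sor-3 (-1.75), ttm-1 (-1.63) and lin-15B (-0.58) ended, and called genes moved for R03D7.2 (-2.67), unc-54 (6.15) and aex-5 (at least 159.9-fold, with 0 counts in N2). Without HC125 replicate 1, the calls of clec-209 (5.41), spds-1 (3.12), fbxa-216 (-2.31), sor-3 (-1.65) and lin-15B (-0.69) ended. Without HC125 replicate 3, those of fbxa-216 (-2.35), R03D7.2 (-2.08), sor-3 (-1.73) and lin-15B (-0.66) ended, and without HC125 replicate 4 those of clec-209 (5.13), fbxa-216 (-2.27), R03D7.2 (-2.02), sor-3 (-1.53) and lin-15B (-0.74). The number of called genes was 30 without N2 replicate 1, 32 without HC125 replicate 4 and 91 without HC125 replicate 2. The excess of lower genes was not stable, with 20 higher and 12 lower without HC125 replicate 4 and 31 and 66 by DESeq2. In the joint omission of N2 replicate 2 and HC125 replicates 1 and 2, an alternative chosen after seeing the data, the calls of unc-54 (6.09, adjusted p = 0.0662), fbxa-216 (-2.85, adjusted p = 0.0964), sor-3 (-1.79, adjusted p = 0.0536) and lin-15B (-0.59, adjusted p = 0.11) ended, and hrde-1 was called (0.48, adjusted p = 0.0381). Library size alone ended the calls of fbxa-216 (-2.33, adjusted p = 0.0518) and lin-15B (-0.68, adjusted p = 0.0973). With only these 2 groups in the fit, 9 of the 17 calls ended, those of R03D7.2, clec-209, lin-15B, mct-2, sor-3, spds-1, suca-1 (-2.03, adjusted p = 0.07) and ttm-1. C04F5.8, not called at -1.47, was called without HC125 replicate 2 (-1.63, adjusted p = 0.0381), by DESeq2 (-1.52, adjusted p = 0.0467) and with no low-count filter (-1.44, adjusted p = 0.0484).

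Among the fixed lists, the systemic RNAi list had 1 of 5 tested members higher in HC125 than in N2 (sid-1, also 1 adjusted over the list alone), with a median log2 fold change of 0.65 and a camera adjusted p of 0.000455, and adjusted p = 0.059 with an estimated correlation. The germline and oocyte list leaned higher with 0 of 39 members called (median 0.21, adjusted p = 0.000867, adjusted p = 0.486 with an estimated correlation). By edgeR 6 of its members had an unadjusted p under 0.05, and by DESeq2 0 were called. Histone genes leaned the same way, with 0 of 71 called by edgeR or DESeq2 and 5 at an unadjusted p under 0.05 (median 0.25, adjusted p = 0.00609, adjusted p = 0.588 with an estimated correlation). Both leans were no larger than differences within HC125. There replicates 1 and 2 differed from 3 and 4 by a median of -0.58 over histone genes and -0.21 over germline and oocyte genes. Lower on balance were the major sperm protein list (0 of 31 called by edgeR or DESeq2, 1 unadjusted, median -0.72, adjusted p = 0.00269) and the spermatogenesis list (0 of 18 by either, 2 unadjusted, median -0.69, adjusted p = 0.0125). Each had adjusted p = 0.588 with an estimated correlation. Both falls rested on N2 replicate 2, in which major sperm protein genes took 0.19% of the counts, against 0.0574% in replicate 1. Without N2 replicate 2 the medians turned to 0.47 and 0.43, and without replicate 1 they were -1.21 and -1.27, an alternative chosen after seeing the data. The nuclear RNAi and WAGO-class list had 0 of 7 called by edgeR, 1 lower adjusted over the list alone, 1 unadjusted and 1 lower by DESeq2 (median -0.22, adjusted p = 0.00683, adjusted p = 0.486 with an estimated correlation). Muscle genes had 1 of 10 higher (unc-54), a median of -0.09, a mean of 0.51 and a test upward (adjusted p = 0.00474), so that the signs differ, and adjusted p = 0.396 with an estimated correlation.

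In the sid-1 neighbourhood 1 of 5 members, sid-1, was higher in HC125 (adjusted over the list alone 1 higher and 1 lower, median 0.11, adjusted p = 0.0241, adjusted p = 0.396 with an estimated correlation). Transformation marker genes had 1 higher, 1 lower and 5 not called (adjusted over the list alone 1 and 2), with a median of -0.55, a mean of 0.25 and no call (adjusted p = 0.582). The lists of the small RNA pathway (0 of 52, 6 unadjusted, adjusted p = 0.263), ERGO-1-class targets (0 of 17, 1 unadjusted, adjusted p = 0.127) and intestine genes (0 of 9, 1 unadjusted, adjusted p = 0.0515) had no member called by edgeR or DESeq2. Neither did the 4 tested genes each of the hypodermis and neuron lists, with 0 unadjusted, which were too few for a set test here and in every other comparison. The table held 0 of the 11 genes of the microRNA list and 0 of the 15363 of the 21U-RNA list, so neither list was tested in any comparison.

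hrde-1;HC125 was compared with HC125 to ask which small RNAs depend on the nuclear Argonaute HRDE-1 (n = 2 and 4). Small RNAs against sid-1 fell by 2.12 ± 0.14 on the log2 scale (SE, adjusted p = 5.64e-09), from 2312 ± 216 to 531.5 ± 36.4 CPM. Small RNAs fell at sosi-1 (-4.01 ± 0.16, adjusted p = 6.70e-12), C38D9.2 (-2.63) and F15D4.5 (-1.96), of the nuclear RNAi and WAGO-class list, in which 4 of 7 genes fell and 1 rose. sosi-1 lies within the span of eri-6, and the strand setting of the counts is not given in the sources used here. Small RNAs against the mechanosensory channel gene trp-4 fell by 7.96 ± 0.24 (adjusted p = 9.02e-13), from 477 ± 38.2 to 1.87 ± 0.03 CPM. Those against tax-4, a cyclic-nucleotide-gated channel of sensory neurons, rose from 0.425 ± 0.849 to 214 ± 9.85 CPM (ratio 722, 95% counting interval 199.5 to 5964).

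Against HC125, 1775 genes were called, 812 higher and 963 lower, of which 149 and 149 differed over 8-fold. 2878 genes had an unadjusted p under 0.05. Scaled by library size alone, 645 were higher and 1194 lower, and the median of all genes moved by -0.119. The count was 1106 without hrde-1;HC125 replicate 1 and 1065 without replicate 2.

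Several genes went from no counts in HC125 to many in hrde-1;HC125. ZC84.7 was at least 81.2-fold higher (35.4 ± 6.17 CPM), T11F9.21 at least 38.3-fold, cank-26 at least 34.8-fold and F36H12.17 at least 22.8-fold, with the floor of 3 counts summed over the group. Y61A9LA.7 rose by 8.29 ± 0.28 (adjusted p = 9.02e-13), and the intraflagellar transport gene ift-20 (ratio 283, interval 78.1 to 2341) and C07G1.7 (ratio 347, interval 62.1 to 13750) rose as well. The largest falls included the hedgehog-related gene grd-16 (ratio 400.3, interval 71.3 to 15870, HC125 over hrde-1;HC125), the chemoreceptor gene srt-69 (329.5, interval 58.6 to 13070), Y110A2AL.1 (-7.57), Y38F2AR.12 (-6.72) and Y37H2A.10 (127, interval 22.2 to 5079). Both copies of srd-73 (WBGene00005137 and WBGene00021570) share their counts and fell (178, interval 48.7 to 1476). DESeq2 did not call tax-4 (adjusted p = 0.202) or C07G1.7 (adjusted p = 0.26). Without HC125 replicate 2, which held all counts of tax-4 in HC125, tax-4 was at least 407-fold higher, and without replicate 4 its ratio was 341 (interval 94.4 to 2821). C07G1.7 was at least 108-fold higher without HC125 replicate 1, with 0 counts left, and had a ratio of 164 (interval 29.4 to 6503) without replicate 4. Without HC125 replicate 1 the ratio of ift-20 was 530.1 (interval 94.9 to 20960).

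**Figure D3:**
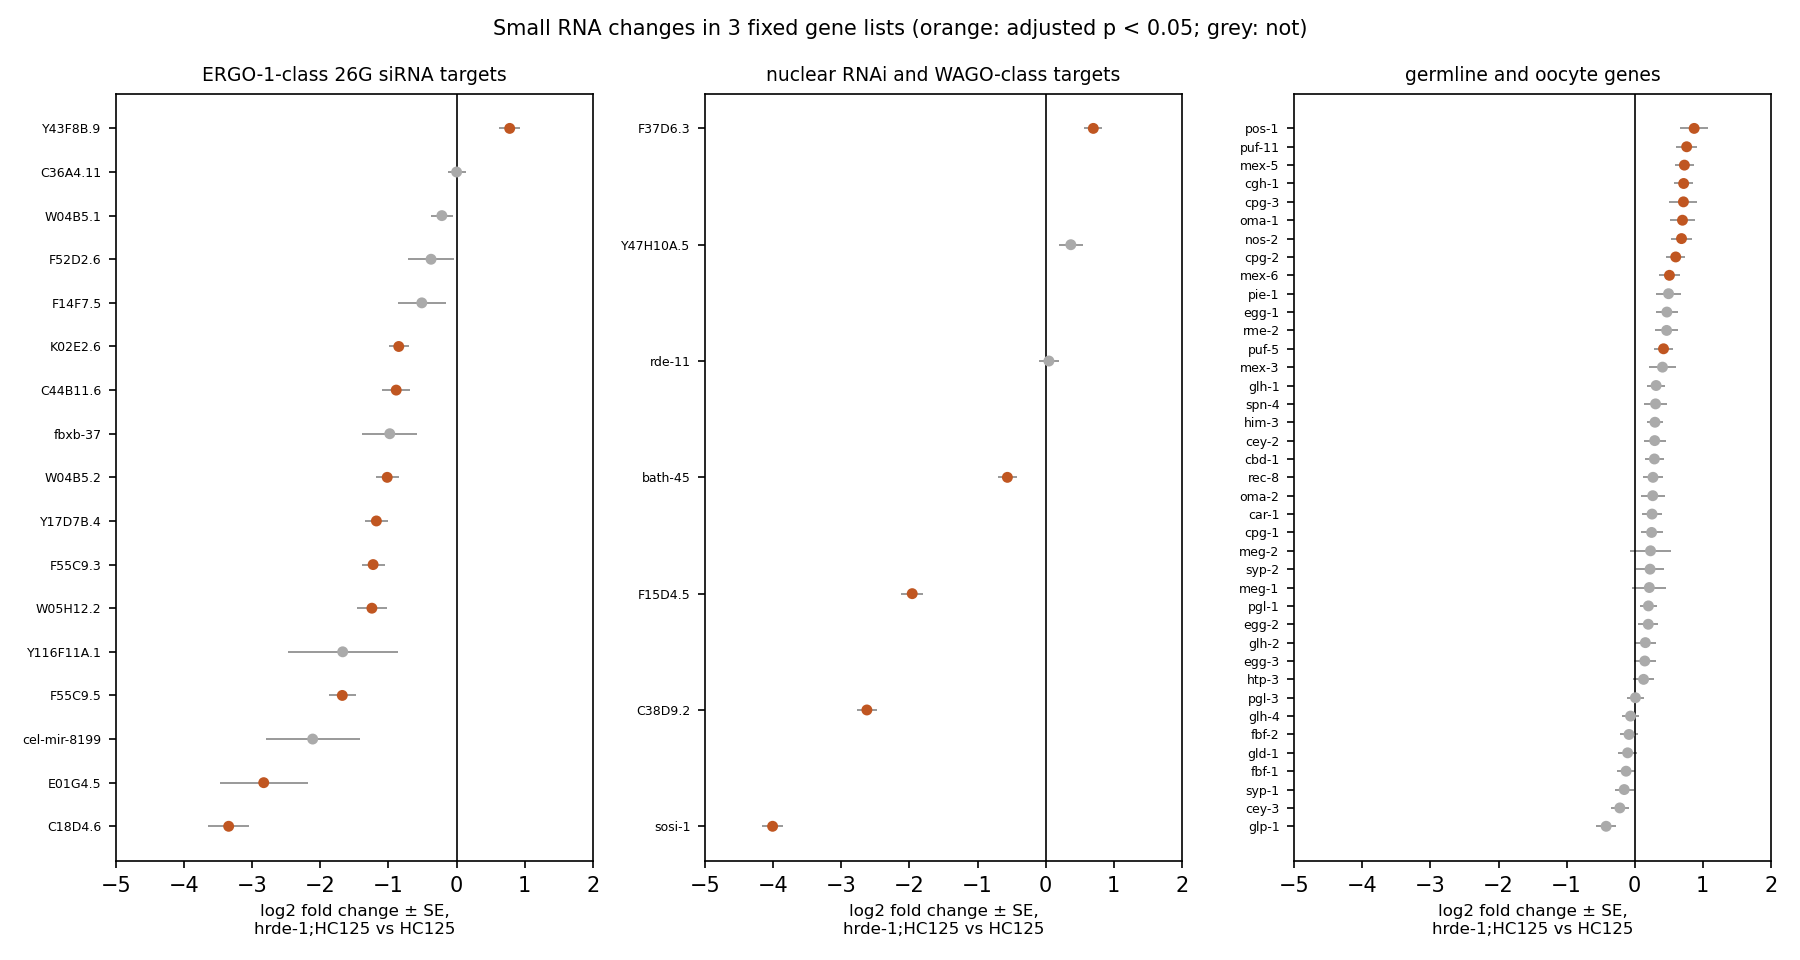
Log2 fold change (hrde-1;HC125 over HC125, with SE bars) of small RNAs against members of the ERGO-1-class, nuclear RNAi and WAGO-class, and germline and oocyte lists, in orange where the adjusted p is under 0.05 and in grey otherwise. sosi-1 at -4.01 and C18D4.6 at -3.35 were the lowest of their lists, and 10 of 39 germline and oocyte genes were higher.

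The nuclear RNAi and WAGO-class list had 4 of 7 members lower, 1 higher (F37D6.3, 0.70) and 2 not called (also 4 and 1 adjusted over the list alone), with a median of -0.56 and a camera adjusted p of 1.54e-06. bath-45 was the fourth to fall (-0.56). Of 17 ERGO-1-class targets, which receive 26G small RNAs, 9 fell, 1 rose and 7 were not called (10 and 1 adjusted over the list alone), with a median of -1.02 (adjusted p = 0.000116). C18D4.6 (-3.35 ± 0.30), F55C9.5 (-1.68), F55C9.3 (-1.23) and Y17D7B.4 (-1.18) were among them. For both lists the call ended, at adjusted p = 0.386 with an estimated correlation. Germline and oocyte genes leaned higher, with 10 of 39 called higher and 0 lower by edgeR (13 and 1 adjusted over the list alone, median 0.27, adjusted p = 0.00671, adjusted p = 0.568 with an estimated correlation). puf-11 (0.76), mex-5 (0.73) and cgh-1 (0.72), which encode RNA-binding and RNA helicase proteins of the germline, rose, as did nos-2 (0.69).

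Of 52 small RNA pathway genes 3 were higher, 5 lower and 44 not called (3 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.774). Small RNAs against the Argonaute gene wago-1 rose by 0.73, and those against rrf-2, of the RNA-dependent RNA polymerase family, and hrde-1 itself fell by 1.08 and 1.01 ± 0.17 (adjusted p = 0.000254). The helicase gene rde-12 fell by 0.50. Of 18 spermatogenesis genes, spe-41 (-2.82) and fer-1 (-3.26) fell (2, also adjusted over the list alone) and 16 were not called (list adjusted p = 0.182). Of 71 histone genes 11 were higher, 11 lower and 49 not called (19 and 13 adjusted over the list alone, median 0.19, adjusted p = 0.756), with falls in his-61 (-1.63), his-68 (-1.60) and his-12 (WBGene00001886 at -1.16 and WBGene00001917 at -1.19). In the sid-1 neighbourhood C04F5.8 rose by 1.62, and sid-1 and C04F5.9 (-1.04) fell (1 and 2 of 5, list adjusted p = 0.182). Against N2, C04F5.8 in hrde-1;HC125 was not called. The tropomyosin gene lev-11 fell by 1.07 and unc-54 rose by 1.07 (1 and 1 of 10 muscle genes, list adjusted p = 0.774). lin-15B fell by 0.92, so that 1 of 7 transformation marker genes was lower and 1 higher (list adjusted p = 0.774). The synaptic vesicle gene rab-3 rose by 1.79 (1 of 4 neuron genes), and sid-1 was the 1 of 5 systemic RNAi genes lower (list adjusted p = 0.209). Neither edgeR nor DESeq2 called any of 31 major sperm protein genes (1 unadjusted, adjusted p = 0.774), 9 intestine genes (0 unadjusted, adjusted p = 0.756) or 4 hypodermis genes (1 unadjusted).

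Of the 44 named genes called beside sid-1 in hrde-1;HC125 against HC125, 37 kept their call when each library was left out. Without hrde-1;HC125 replicate 1, the calls of srd-73 (1 count left), rde-12 (-0.45), lev-11 (-1.09) and unc-54 (0.41) ended. With 0 counts left, grd-16 was at least 50.5-fold lower and srt-69 at least 41.6-fold, Y37H2A.10 had a ratio of 48.1 (interval 8.41 to 1921), and C18D4.6 was at -4.11. Without hrde-1;HC125 replicate 2, those of srd-73 (1 count left), rde-12 (-0.56), nos-2 (0.61), lev-11 (-1.07) and rab-3 (1.53) ended, and Y37H2A.10, with 0 counts left, was at least 26.4-fold lower. The call of unc-54 also ended without HC125 replicate 1 (1.05, adjusted p = 0.0544) and in the joint omission of 3 libraries (1.14, adjusted p = 0.134).

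hrde-1;HC125 was also compared with N2 to set the mutant against wild type without the array (n = 2 and 2). At sid-1 they fell by 0.61 ± 0.15 on the log2 scale (SE, adjusted p = 0.0106), from 811 ± 35.9 to 531.5 ± 36.4 CPM, and those against hrde-1 fell by 0.73 ± 0.19 (adjusted p = 0.012). Small RNAs against trp-4 fell by 8.28 ± 0.25 (adjusted p = 1.32e-12) and those against sosi-1 fell to a log2 fold change of -4.18 (adjusted p = 1.84e-11). Small RNAs counted at unc-54 rose by 6.04 ± 0.44 (adjusted p = 1.96e-06). tax-4, with 0 counts in N2, was at least 89.3-fold higher, and ift-20 at least 35.0-fold.

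Against N2, 1857 genes were called, 926 higher and 931 lower, of which 174 and 201 differed over 8-fold. 3311 genes had an unadjusted p under 0.05. Scaled by library size alone, 701 were higher and 1060 lower, and the median of all genes moved by -0.1. The count was 1226 without hrde-1;HC125 replicate 1 and 1045 without replicate 2.

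With 0 counts in N2, C07G1.7 was at least 21.5-fold higher, ZC84.7 at least 15.1-fold, Y43D4A.2 at least 14.98-fold, F54C9.7 at least 14.04-fold, T10G3.1 at least 13.6-fold and the pseudogene C18H2.4 at least 10.96-fold. Neither tax-4 (adjusted p = 0.221) nor C07G1.7 (adjusted p = 0.336) was called by DESeq2. Small RNAs fell for grd-16 (ratio 716, interval 125.4 to 28600, N2 over hrde-1;HC125), srt-69 (498, interval 86.3 to 19990), Y110A2AL.1 (-7.66), E02H9.9 (-6.93) and the pseudogenes Y73B3A.7 (-7.45), ZK218.8 (249, interval 41.6 to 10150) and M01E5.1 (202.5, interval 33.3 to 8300).

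Of the ERGO-1-class targets 9 of 17 were lower, 1 higher and 7 not called, also 9 and 1 adjusted over the list alone (median -1.23, adjusted p = 1.595e-05, adjusted p = 0.286 with an estimated correlation). C18D4.6 (-3.71), F55C9.5 (-1.65), Y17D7B.4 (-1.46) and K02E2.6 (-1.26) fell. In the nuclear RNAi and WAGO-class list 4 of 7 fell and 3 were not called, also 4 adjusted over the list alone, with sosi-1, C38D9.2 (-2.85), F15D4.5 (-2.16) and bath-45 (-0.79). That list had a median of -0.79 (adjusted p = 1.68e-09, adjusted p = 0.177 with an estimated correlation). Germline and oocyte genes were higher in 15 of 39 and lower in 0 by edgeR (18 and 0 adjusted over the list alone, median 0.50, adjusted p = 8.04e-05, adjusted p = 0.513 with an estimated correlation), with cgh-1 (1.20), puf-11 (1.20), mex-5 (1.175) and cpg-2 (0.92) among them. Of 18 spermatogenesis genes, spe-41 (-3.09) and fer-1 (-3.59) fell, also 2 adjusted over the list alone (median -1.01, adjusted p = 0.0226, adjusted p = 0.945 with an estimated correlation). Without N2 replicate 2 that median turned to 0.42 (adjusted p = 0.575).

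Small RNA pathway genes were higher in 3, lower in 6 and not called in 43 (also 3 and 6 adjusted over the list alone, list adjusted p = 0.844), with wago-1 at 0.74, rrf-2 at -1.37 and the helicase gene eri-6 at -0.63. Histone genes were higher in 16, lower in 9 and not called in 46 (22 and 10 adjusted over the list alone, list adjusted p = 0.186), with falls in his-61 (-1.66), his-68 (-1.48), his-12 (WBGene00001886, -1.13) and his-24 (-1.035). The transformation marker genes lin-15A (-1.89) and lin-15B (-1.63) fell and unc-54 rose, so that 1 of 7 was higher and 2 lower (1 and 3 adjusted over the list alone). Their median was -1.3, their mean 0.10 and their test downward (adjusted p = 0.844). Muscle genes had 1 of 10 higher, a median of -0.21, a mean of 0.39 and a test upward (adjusted p = 0.49). In the systemic RNAi list sid-1 was the 1 of 5 lower (1 higher and 1 lower adjusted over the list alone), with a median of -0.08, a mean of 0.25 and a test upward (adjusted p = 0.98), and in the neighbourhood it was the 1 of 5 lower (adjusted p = 0.509). rab-3 rose by 1.67 (1 of 4 neuron genes). Major sperm protein genes had 0 of 31 called by edgeR or DESeq2 (0 unadjusted, adjusted p = 0.504). Their median was -1.02 without N2 replicate 1 and turned to 0.55 without N2 replicate 2. Neither tool called any of 9 intestine genes (2 unadjusted, adjusted p = 0.29) or 4 hypodermis genes (1 unadjusted).

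Of the 42 named genes called beside sid-1 in hrde-1;HC125 against N2, 39 kept their call when each library was left out. Without hrde-1;HC125 replicate 1, the calls of hrde-1 (-0.63, adjusted p = 0.11) and rab-3 (1.89) ended, C18D4.6 was at -4.48 and unc-54 at 5.39. With 0 counts left in hrde-1;HC125, grd-16 was at least 90.3-fold lower, srt-69 at least 62.8-fold and ZK218.8 at least 31.4-fold, and with 0 counts in N2, ift-20 was at least 25.9-fold higher. With 1 count left, Y73B3A.7 had a ratio of 536 (interval 95.02 to 21290) and M01E5.1 of 76.6 (interval 12.6 to 3140). Without hrde-1;HC125 replicate 2, those of sid-1 (-0.58, adjusted p = 0.089), eri-6 (-0.57) and rab-3 (1.41) ended, and M01E5.1, with 0 counts left, was at least 41.96-fold lower. Without N2 replicate 1 rab-3 was not called (1.41), and without N2 replicate 2 it was not called either (2 counts left in N2) and unc-54 was at 7.24. With only these 2 groups in the fit, the call of eri-6 ended (-0.67, adjusted p = 0.0752). The call of rab-3 also ended under median-of-ratios scaling (1.62), library size alone (1.57), the 10 CPM filter (1.59) and DESeq2 (1.64), and in the joint omission, in which C04F5.9 was called (-0.79, adjusted p = 0.0487).

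The non-array lines were compared between generation F6, labelled silenced, and F21, labelled de-silenced, to ask which small RNAs go with the silenced state (n = 2 and 2). State and generation change together here, so their effects cannot be told apart. Small RNAs against sid-1 were higher at F6 by 2.54 ± 0.16 on the log2 scale (SE, adjusted p = 1.57e-07), at 4446 ± 406 against 766 ± 49.6 CPM. Those against the neighbouring gene C04F5.9 were higher by 3.25 ± 0.26 (adjusted p = 4.37e-06), at 486 ± 93.2 against 48.8 ± 8.55 CPM. Y54E5A.8 was higher by 2.35 ± 0.24 (adjusted p = 6.53e-05), and the histone gene his-61 was lower by 1.84 ± 0.23 (adjusted p = 0.000973), at 51.2 ± 3.36 against 181 ± 17.01 CPM.

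In all 15 genes were called, 9 higher and 6 lower at F6, and 290 had an unadjusted p under 0.05. Also higher were dhs-9 of the short-chain dehydrogenase family (2.76), R07E5.4 (1.72), Y17G7B.8 (1.65) and, of the mitochondrial genome, MTCE.34 (1.59, 262.5 ± 22.4 against 82.7 ± 23.5 CPM) and MTCE.4 (1.45). Mitochondrial genes took 1.83 ± 0.106% of the counts at F6 and 0.698 ± 0.242% at F21. Among HC125 replicates alone that share ran from 0.738 to 1.71%. Lower were H14A12.5 (-1.57), Y56A3A.7 (-1.55) and the histone genes his-51 (WBGene00001895 at -1.5 and WBGene00001925 at -1.41) and his-7 (-1.42).

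Beside sid-1, 3 of the 13 named genes called between F6 and F21 kept their call when each library was left out: C04F5.9, Y54E5A.8 and his-61. Without F6 replicate 1, the calls of dhs-9 (2.18), R07E5.4 (1.80), Y17G7B.8 (1.25), MTCE.34 (1.52), MTCE.4 (1.44), H14A12.5 (-1.55), Y56A3A.7 (-1.66), his-51 (-1.63 and -1.49) and his-7 (-1.49) ended. Without F6 replicate 2, those of R07E5.4 (1.66), MTCE.4 (1.5), H14A12.5 (-1.61), Y56A3A.7 (-1.44), his-51 (-1.38 and -1.32) and his-7 (-1.35) ended. Without F21 replicate 1, those of dhs-9 (2.56), R07E5.4 (2.22), Y17G7B.8 (1.86), H14A12.5 (-1.74), Y56A3A.7 (-1.56), his-51 (-1.72 and -1.58) and his-7 (-1.66) ended, and MTCE.4 was at 2.46. Without F21 replicate 2, those of R07E5.4 (1.62), Y17G7B.8 (1.60), MTCE.34 (1.4), MTCE.4 (1.22), H14A12.5 (-1.47), Y56A3A.7 (-1.52), his-51 (-1.36 and -1.29) and his-7 (-1.25) ended. The number of called genes was 6 without F6 replicate 1 and 8 without F6 replicate 2. The excess of higher genes turned to 52 higher and 88 lower with no low-count filter and 42 and 55 with only these 2 groups in the fit. The call of Y17G7B.8 also ended with library size alone (1.61) and the 10 CPM filter (1.64), and that of dhs-9 with only these 2 groups in the fit (2.77).

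The sid-1 neighbourhood list was called higher at F6 through sid-1 and C04F5.9, 2 of its 5 members (2 higher and 1 lower adjusted over the list alone, median 1.15, adjusted p = 5.395e-24, adjusted p = 0.000624 with an estimated correlation). Of the 5 members 3 were positive and 2 negative. The median was that of ugt-63, near the floor with 10 counts in each F6 library and 6 and 0 at F21. Through sid-1 the systemic RNAi list was higher too, with 1 of 5 called, also 1 adjusted over the list alone (median 0.05, adjusted p = 7.62e-10, adjusted p = 0.00268 with an estimated correlation). Histone genes were higher in 0, lower in 4 of 71 and not called in 67 (14 lower adjusted over the list alone, 10 lower by DESeq2), with a median of 0.03, a mean of -0.19 and a test downward (adjusted p = 2.34e-07, adjusted p = 0.547 with an estimated correlation). Muscle genes leaned higher with 0 of 10 called by edgeR or DESeq2 and 3 unadjusted (median 1.23, adjusted p = 3.11e-06, adjusted p = 0.0845 with an estimated correlation), as did intestine genes with 0 of 9 called by either and 3 unadjusted (median 0.48, adjusted p = 3.11e-06, adjusted p = 0.23 with an estimated correlation). The major sperm protein list (0 of 31 by either, 1 unadjusted, median -0.58, adjusted p = 2.34e-07) and the spermatogenesis list (0 of 18 by either, 0 unadjusted, median -0.61, adjusted p = 0.00241) leaned lower, each at adjusted p = 0.547 with an estimated correlation. Neither edgeR nor DESeq2 called a member of the small RNA pathway (52 tested, 0 unadjusted, list adjusted p = 0.993), ERGO-1-class (17, 0 unadjusted, 0.993) or nuclear RNAi and WAGO-class list (7, 0 unadjusted, 0.907). The same held for the germline and oocyte (39, 1 unadjusted, 0.854) and transformation marker lists (7, 1 unadjusted, 0.745, median -0.12, mean 0.31, test upward) and for the 4 tested genes each of the hypodermis and neuron lists (0 unadjusted).

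F6 was compared with N2 to set the silenced line against wild type (n = 2 and 2). At sid-1 small RNAs were higher at F6 by 2.46 ± 0.16 on the log2 scale (SE, adjusted p = 1.38e-07) and those against C04F5.9 by 2.91 ± 0.26 (adjusted p = 7.60e-06). The nuclear hormone receptor gene nhr-64 rose by 3.14 ± 0.27 (adjusted p = 3.44e-06) and B0261.8 by 3.14 ± 0.23 (adjusted p = 5.24e-07), from 120 ± 25.04 to 1036 ± 7.78 CPM. Small RNAs against arl-13, a small GTPase of cilia, fell by 4.22 ± 0.26 (adjusted p = 1.26e-07), from 171 ± 10.1 to 9.15 ± 0.6252 CPM. Those against the histone genes his-61 (-2.62), his-51 (-2.40 for both WBGene00001895 and WBGene00001925) and his-7 (-2.31) fell.

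In all 150 genes were called, 40 higher and 110 lower, and 2053 had an unadjusted p under 0.05. Both copies of srd-71 (4.54), spds-1 (3.91), the 2 genes named F56A4.12 (WBGene00021226 at 3.11 and WBGene00018920 at 3.10) and the riboflavin transporter gene rft-1 (3.06) were higher. Lower were C55C3.4 (ratio 65.6, interval 16.4 to 572, N2 over F6), Y6E2A.10 (55.1, interval 13.5 to 485), T28C6.5 (29.8, interval 8.61 to 158.5), C35E7.10 (-5.001), dct-9 (-4.56), Y69E1A.8 (-4.355) and W03G1.2 (-4.25).

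Major sperm protein genes were lower in 2 of 31 and not called in 29 (29 lower adjusted over the list alone, 22 by DESeq2), with a median of -2.15 (adjusted p = 2.92e-19, adjusted p = 0.261 with an estimated correlation), msp-38 at -2.97 and msp-152 at -2.52. Spermatogenesis genes were lower in 2 of 18 and not called in 16 (12 lower adjusted over the list alone, 10 by DESeq2), with a median of -2.15 (adjusted p = 7.18e-09, adjusted p = 0.261 with an estimated correlation), nspd-1 at -2.998 and ssp-19 at -2.62. alg-3, an Argonaute gene of spermatogenesis, fell by 3.49 and was the 1 of 52 small RNA pathway genes called lower (1 higher and 1 lower adjusted over the list alone, list adjusted p = 0.13). The sperm genes moved with N2 replicate 2, in which major sperm protein genes took 0.19% of the counts against 0.0574% in replicate 1 and 0.0295 ± 0.00126% at F6. Without N2 replicate 2 the medians were -0.91 for the major sperm protein list and -0.68 for the spermatogenesis list. That leaves 1 N2 library, and no test with an estimated correlation was run there, so only the medians are given. Histone genes were lower in 15 of 71 and not called in 56 (16 lower adjusted over the list alone, 16 by DESeq2, median -0.15, mean -0.50, adjusted p = 5.80e-11, adjusted p = 0.443 with an estimated correlation). The sid-1 neighbourhood had 2 of 5 higher, sid-1 and C04F5.9 (2 higher and 1 lower adjusted over the list alone, median 0.48, adjusted p = 1.61e-08, adjusted p = 0.0172 with an estimated correlation). The systemic RNAi list had 1 of 5 higher, sid-1, also 1 adjusted over the list alone (median 0.46, adjusted p = 1.47e-05, adjusted p = 0.0172 with an estimated correlation).

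Germline and oocyte genes leaned higher at F6 than in N2 with 0 of 39 called by edgeR or DESeq2 and 5 unadjusted (median 0.19, adjusted p = 0.00546, adjusted p = 0.468 with an estimated correlation). Intestine genes leaned lower with 0 of 9 called by either and 1 unadjusted (median -0.46, adjusted p = 0.0478, adjusted p = 0.505 with an estimated correlation). By edgeR 0 of 17 ERGO-1-class targets were called, 1 lower adjusted over the list alone, 5 unadjusted and 2 lower by DESeq2 (median -0.05, mean 0.11, test downward, adjusted p = 0.494). Neither edgeR nor DESeq2 called a member of the nuclear RNAi and WAGO-class (7 tested, 0 unadjusted, list adjusted p = 0.494), muscle (10, 1 unadjusted, 1 higher adjusted over the list alone, 0.73, median -0.05, mean 0.01, test upward) or transformation marker list (7, 1 unadjusted, 0.257). The same held for the 4 tested genes each of the hypodermis and neuron lists (0 unadjusted).

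Beside sid-1, 11 of the 26 named genes called between F6 and N2 kept their call when each library was left out. Without N2 replicate 2, the calls of spds-1 (3.38), C35E7.10 (-4.09), Y69E1A.8 (-3.50), alg-3 (-2.65), ssp-19 (-1.82), nspd-1 (-1.84), msp-38 (-1.42) and msp-152 (-1.59) ended, as did those of F56A4.12, C55C3.4, Y6E2A.10, dct-9, T28C6.5 and W03G1.2, each with 1 to 3 counts left in a group, and nhr-64 was at 4.19. Without N2 replicate 1, Y6E2A.10 (ratio 77.6, interval 18.7 to 687), dct-9 (-5.31), W03G1.2 (-4.89) and msp-38 (-3.57) kept their calls. Without F6 replicate 1, those of Y69E1A.8 (-3.77), W03G1.2 (-3.82), alg-3 (-3.05), ssp-19 (-2.59), nspd-1 (-3.04), msp-38 (-2.84) and msp-152 (-2.35) ended, as did those of Y6E2A.10, C35E7.10, dct-9 and T28C6.5, each with 1 to 3 counts left. Without F6 replicate 2, those of spds-1 (3.82), alg-3 (-4.17), ssp-19 (-2.65), nspd-1 (-2.95), msp-38 (-3.11) and msp-152 (-2.71) ended, as did those of C55C3.4, Y6E2A.10, C35E7.10, dct-9, T28C6.5, Y69E1A.8 and W03G1.2, each with 1 to 3 counts left. The number of called genes was 586 without N2 replicate 1 (175 higher, 411 lower), 35 without N2 replicate 2 (12 and 23), 42 without F6 replicate 1 (20 and 22) and 35 without F6 replicate 2 (18 and 17). In the joint omission of N2 replicate 2 and HC125 replicates 1 and 2 it was 252 (138 and 114), so the excess of lower genes was not stable, and the calls of F56A4.12, Y6E2A.10, dct-9, T28C6.5, Y69E1A.8, W03G1.2, alg-3, ssp-19, nspd-1, msp-38 and msp-152 ended. With the 10 CPM filter, Y6E2A.10, T28C6.5, Y69E1A.8 (-4.42) and msp-152 (-2.59) were not called.

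F21 was compared with N2 to set the de-silenced line against wild type (n = 2 and 2). Small RNAs against sid-1 did not differ beyond the spread between replicates, at 766 ± 49.6 and 811 ± 35.9 CPM and a log2 fold change of -0.08 ± 0.16 (SE, adjusted p = 0.846). Both copies of srd-71 rose by 4.57 ± 0.38 (adjusted p = 3.89e-06), nhr-64 by 3.055 ± 0.28 (adjusted p = 8.40e-06) and B0261.8 by 2.99 ± 0.23 (adjusted p = 3.47e-06). Small RNAs against arl-13 fell by 3.20 ± 0.27 (adjusted p = 4.51e-06), from 171 ± 10.1 to 23.75 ± 13.15 CPM.

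In all 21 genes were called, 12 higher (9 distinct names, the rest second copies) and 9 lower, and 1489 had an unadjusted p under 0.05. Also higher were spds-1 (4.27), F56A4.12 (2.75 for both IDs) and F55A11.6 (2.675), and lower were WBGene00019555 (-2.17), which is not in the annotation, pqn-52 (-1.87), ttn-1 (-1.765), C06B8.7 (-1.48), ril-2 (-1.30), MTCE.34 (-1.29) and best-25 (-1.29).

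Beside these, intestine genes leaned lower at F21 with 0 of 9 called by edgeR, 6 lower adjusted over the list alone, 7 unadjusted and 3 lower by DESeq2 (median -0.97, adjusted p = 6.96e-08, adjusted p = 0.398 with an estimated correlation). Major sperm protein genes leaned lower with 0 of 31 called by edgeR or DESeq2 and 17 unadjusted (median -1.52, adjusted p = 1.41e-10), and spermatogenesis genes with 0 of 18 called by edgeR, 2 lower adjusted over the list alone, 7 unadjusted and 1 lower by DESeq2 (median -1.57, adjusted p = 1.23e-05). Each had adjusted p = 0.398 with an estimated correlation. These too rested largely on N2 replicate 2, without which the medians were -0.40 (adjusted p = 0.161) and -0.16 (adjusted p = 0.314). Muscle genes leaned lower with 0 of 10 called by edgeR, 3 unadjusted and 1 lower by DESeq2 (median -1.09, adjusted p = 0.0285, adjusted p = 0.398 with an estimated correlation). Histone genes leaned lower with 0 of 71 called by edgeR, 11 lower adjusted over the list alone, 15 unadjusted and 5 lower by DESeq2 (median -0.195, adjusted p = 7.46e-05, adjusted p = 0.635 with an estimated correlation). Germline and oocyte genes leaned higher with 0 of 39 called by edgeR or DESeq2 and 5 unadjusted (median 0.22, adjusted p = 0.000842, adjusted p = 0.398 with an estimated correlation). Transformation marker genes had 0 of 7 called by edgeR, 2 unadjusted and 1 lower by DESeq2 (list adjusted p = 0.106). Neither tool called a member of the systemic RNAi list (5 tested, 0 unadjusted, list adjusted p = 0.546), the small RNA pathway (52, 6 unadjusted, 0.106) or the ERGO-1-class targets (17, 1 unadjusted, 0.505, median -0.12, mean 0.04, test downward). The same held for the nuclear RNAi and WAGO-class list (7, 0 unadjusted, 0.546), the sid-1 neighbourhood (5, 0 unadjusted, 0.582) and the 4 tested genes each of the hypodermis (1 unadjusted) and neuron lists (0 unadjusted).

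Of the 16 named genes called between F21 and N2, 5 kept their call when each library was left out: srd-71 under both IDs, nhr-64, B0261.8 and arl-13. Without F21 replicate 1, the calls of spds-1 (4.09), F56A4.12 (2.29), F55A11.6 (2.82), WBGene00019555 (-2.54), pqn-52 (-1.83), ttn-1 (-1.67), C06B8.7 (-1.09), MTCE.34 (-1.70) and best-25 (-1.40) ended, and arl-13 was at -2.38. Without F21 replicate 2, those of F55A11.6 (2.64), ttn-1 (-1.78), ril-2 (-1.16), MTCE.34 (-1.08) and best-25 (-1.23) ended. Without N2 replicate 1, those of F56A4.12 (2.73), F55A11.6 (3 counts left in N2) and C06B8.7 (-1.17) ended. Without N2 replicate 2, those of spds-1 (3.74), F56A4.12 (3 counts left in N2), F55A11.6 (1 count left), MTCE.34 (-1.22) and best-25 (-1.31) ended, and nhr-64 was at 4.09. The number of called genes was 9 without F21 replicate 1 and 107 without N2 replicate 1, and the excess of higher genes turned to 28 higher and 66 lower by DESeq2. The joint omission ended the calls of F56A4.12 and F55A11.6. F55A11.6 was not called by DESeq2 (2.65, adjusted p = 0.0819) or with only these 2 groups in the fit (adjusted p = 0.114), which also ended the call of C06B8.7 (-1.53, adjusted p = 0.064).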

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

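All tests of explanations reported here were chosen after the results were seen.

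Small RNAs counted at aex-5 and unc-54 were far higher in the 6 array libraries than in the 6 others, the split for which they were picked. A general rise of small RNAs against muscle genes is argued against, since the other 9 tested muscle genes had a median log2 fold change of -0.17 (SD 0.64) in HC125 against N2. Low depth of the other libraries is argued against, since the lowest array library exceeded the highest deep non-array library at least 35.3 times. Small RNAs against sequence carried by the array may have been counted at these genes, whose 20 flanking tested genes had a median of 0.00, though that would not cover prx-11, lower in the same 6 libraries (12.4 to 47.5 CPM against at least 183). That stays open, since counts per gene hold no positions and the make-up of the array is not given in the sources used here.

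On chromosome V a segment with a second copy beside it (V:2348215-2560739, 25 tested genes, 14 with distinct counts) had medians of 2.73, 2.67 and 2.80 on the log2 scale against N2 in HC125, F6 and F21, with 5, 4 and 3 of the 14 called higher and Y19D10A.4 negative in each. Counts in proportion to a doubled copy number are argued against by the lowest of these medians, 2.67. Low depth of N2 is argued against by a ratio of at least 2.37 in other libraries no deeper than N2, and a change of the whole chromosome arm by flanking genes, whose highest median was -0.08. In hrde-1;HC125 the 14 genes were all lower than in HC125, with a median of -2.88, but there flanking genes moved too (median -0.77, SE 0.34, 7 of 20 lower and 1 higher, and -0.87 with 6 lower against N2, where the segment was at 0.03). A difference between the N2 animals and the other strains stays open, and the segment was itself picked from these values.

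Small RNAs against sperm genes differed between replicates: N2 replicate 2 exceeded replicate 1 by a median of 1.63 over the spermatogenesis list and 1.43 over the major sperm protein list. HC125 samples 1 and 2 exceeded samples 3 and 4 by 1.01 and 1.14, while in N2 and HC125 muscle genes differed by 0.70 and 0.29, germline and oocyte genes by 0.16 and -0.21 and histone genes by -0.23 and -0.58. The 1 pair of N2 libraries prompted the question. Its deeper library had 3.31 times the share of major sperm protein counts of the shallower (95% counting interval 2.91 to 3.78). A higher share did not go with low depth in that pair, but the interval covers counting error only. In HC125 the shallower had the higher share in 6 of 6 pairs, which reuse 4 samples, as in the pairs at F6 and F21 but not in hrde-1;HC125, so low depth stays open there. A different share of sperm-producing animals or germ cells may account for it, with the smaller median difference at 1.01, and stays open since the labels give no measure of it and muscle and histone genes differed as well.

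The difference between groups was itself tested at sid-1 and C04F5.9. The effect against N2 was larger at F6 than in HC125 by 0.94 ± 0.13 at sid-1 (adjusted p = 0.000405) and by 2.51 ± 0.19 at C04F5.9 (adjusted p = 1.19e-06). It was larger at F6 than at F21 by 2.54 at sid-1 and by 3.25 at C04F5.9, the values already given for F6 against F21. N2 drops out of both differences, which are direct contrasts between the groups and no further test. In HC125, small RNAs against any sid-1 sequence on the array may be counted at sid-1 too.

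Over the same 4 HC125 samples 62 values were checked, and in 6 of them 1 sample lay far from the others. The 62 reuse the same samples and include second copies with identical values. A chance rate of 5% therefore does not apply to their number. HC125 1 had 30.1 CPM at suca-1 against 14.4 to 15.5 in the others, 3060 at F37D6.3 against 2705 to 2752, and 15.1 at rab-3 against 3.89 to 5.52. It had 2.15 CPM at both C07G1.7 and ift-20, and HC125 2 had 1.7 CPM at tax-4, while the other HC125 samples lay at 0 to 0.263. Those 3 values are 1 or 2 counts each, under the floor of 3 counts, set against 0 or 1, so they are no measured difference.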

How the results depend on the processing

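Of the settings reported here, the joint omission of N2 replicate 2 and HC125 replicates 1 and 2, which stood apart on the second principal component, was chosen after seeing the data, and so was the omission of each N2 library for the sperm lists. Of 163 alternatives for the gene counts, list counts and sid-1, 118 kept their side of the threshold or lay within 1.5 times, 44 moved and 1 was weaker. Of 2332 for named genes, the sperm lists and the mitochondrial, histone and major sperm protein shares of counts, 2083 stayed, 209 lost their call, 6 gained it and 34 turned direction. The shares counted as staying where leaving out a library moved their mean by less than the SD. In groups of this size that cannot fail, so their part of the count shows nothing. Without a low-count filter, which tests more genes, 256 genes were called in HC125 against N2, 140 between F6 and F21, 1183 between F6 and N2 and 662 between F21 and N2. With the replicate number as a block, 42, 842 and 172 genes were called in the last 3, and the named calls of fbxa-216 (-2.20), sor-3 (-1.55), R03D7.2 (-1.84), lin-15B (-0.67) and unc-54 (5.01), 5 of 17, in HC125 against N2 and of unc-54 (0.93) and rab-3 (1.31) in hrde-1;HC125 against HC125 ended. The block called 27 higher and 16 lower genes in HC125 against N2 and 17 and 25 between F6 and F21. Whether equal numbers pair samples is not given in the sources used here: over 20 pairs correlations ran from -0.254 to 0.312, 2 of them over 0.1, and 7 of 10 libraries correlated best with one of their own number. These were correlations of deviations from group means, which mirror each other in a group of 2. Some pairs and libraries were thus counted more than once, and the check does not decide it. In the order of the samples, HC125 1 and 2 alternate with N2, and HC125 3 and 4 with hrde-1;HC125. Whether that order marks a batch is not given either. A pairing of hrde-1;HC125 with HC125 3 and 4 was not tried. DESeq2 called 97, 39, 543 and 94 genes in those 4 comparisons, and a fit of only the 2 groups 18, 97, 554 and 37. The joint omission gave 488 genes in HC125 against N2, 252 between F6 and N2 and 143 between F21 and N2. Only HC125 had replicates 3 and 4, so the block gave each its own term, and its HC125 estimates rested on replicates 1 and 2. Any further cause of the changes with the block was not tested. For DESeq2, the fit of 2 groups and the joint omission the cause was not tested either.

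Leaving out each library in turn gave 30 to 91 genes in HC125 against N2, 1065 to 1779 in hrde-1;HC125 against HC125, 1045 to 1429 in hrde-1;HC125 against N2, 6 to 14 between F6 and F21, 35 to 586 between F6 and N2 and 9 to 107 between F21 and N2. A lone sample left in a group was assumed to vary like the other groups. In the same order sid-1 ranged from 1.45 to 1.57, -2.18 to -2.08, -0.68 to -0.57, 2.46 to 2.63, 2.38 to 2.51 and -0.13 to -0.02, and lost its call only without hrde-1;HC125 replicate 2 against N2 (-0.58). Lists called with an estimated correlation numbered 0, 0, 0, 2, 2 and 0, and by fry, which does not compare a list with other genes, 1, 5, 3, 2, 2 and 0, against 8, 3, 4, 7, 7 and 6 with the preset one.

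All genes whose values turned direction were not called, and the cause was not tested. Ranges are over libraries left out in turn. ugt-63 had 3 counts in N2, all in replicate 1, and 0 in F21 replicate 2, so its highest values against N2 and its lowest between F21 and N2 were fitted against 0 counts, depend on the prior count and are no fold. In HC125 against N2, ugt-63 was at -0.92 with the block, -0.97 in the joint omission and -1.30 to 5.82 over libraries, F14F9.4 at 0.54 with the block and -0.83 to 0.44, and C04F5.9 at -0.05 in the joint omission. In hrde-1;HC125 against HC125, ugt-63 was at 0.98 with the block, 0.06 by DESeq2 and -1.35 to 0.71 over libraries, and F14F9.4 at 0.12 in the joint omission. In hrde-1;HC125 against N2, ugt-63 was at -0.00 with median-of-ratios scaling, -0.04 with library size, -0.13 by DESeq2, -1.39 in the joint omission and -1.36 to 5.76 over libraries, C04F5.8 at -0.05 to 0.31 and F14F9.4 at -1.23 to 0.03. Between F6 and F21, hrde-1 was at -0.00 with library size, and F14F9.4 at 0.00 with the block and -0.32 to 0.37 over libraries. Between F6 and N2, ugt-63 was at -1.1 in the joint omission and -1.13 to 5.98 over libraries, and F14F9.4 at -0.12 and -0.15 to 1.1. Between F21 and N2, ugt-63 was at -5.54 to 4.82 over libraries, F14F9.4 at -0.01 to 1.25 and C04F5.8 at -0.26 to 0.07. Over the N2 libraries left out, the medians of the spermatogenesis and major sperm protein lists ran from -1.27 to 0.43 and -1.21 to 0.47 in HC125 and from -1.53 to 0.42 and -1.02 to 0.55 in hrde-1;HC125, positive without N2 replicate 2.

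Scaling to microRNA counts was not run, since only 1 gene of the table was annotated as a microRNA, with 0.00394% of the counts, and neither were the alternatives for the 5'-dependent libraries. Depth limits what can be seen: 3 counts came to 6.65 CPM in the shallowest library.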

Other observations

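The enrichment and overlap tests reported here were chosen after the results were seen. In hrde-1;HC125 against HC125, small RNAs fell more often against genes of the X chromosome, which is largely silent in the germline: 174 of 990 tested genes were lower, 17.6% against 8.32% elsewhere (odds ratio 2.35, 95% interval 1.95 to 2.82, Fisher's exact test, adjusted p = 3.26e-17). Fewer X genes were higher (38, odds ratio 0.449, adjusted p = 7.4e-07). Pseudogenes were lower in 57 of 241, 23.7% against 8.86% of other genes (odds ratio 3.19, interval 2.31 to 4.35, adjusted p = 1.04e-10). Chromosome IV was lower less often (odds ratio 0.58, adjusted p = 1.94e-07), as were II (0.746, adjusted p = 0.00477) and III (0.785, adjusted p = 0.0211), and II was higher more often (1.26, adjusted p = 0.0236, but 0.506 with library size alone). Chromosome V was lower more often (odds ratio 1.4, adjusted p = 0.000234), and still so without the 25 genes of its duplicated segment, all of them lower (odds ratio 1.23, interval 1.03 to 1.47, unadjusted p = 0.0182). Genes are not independent.

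HC125, F6 and F21 shared calls against the same 2 N2 libraries. HC125 and F6 shared 15 higher genes (11 distinct names, the rest second copies) and 7 lower, HC125 and F21 10 higher (7 distinct) and 2 lower, and F6 and F21 12 higher (9 distinct) and 7 lower. In 20 simulated draws without change and with the same N2 libraries shared, at most 1 gene was shared. With no gene changed such draws give few calls to share. They cannot show how far noise in the N2 libraries reaches several lists of real calls. Among the shared genes, B0261.8, nhr-64, rft-1, spds-1 and, in the duplicated segment of chromosome V, srd-71, C01B4.6 and F56A4.12 were higher in all 3, and pqn-52 and ttn-1 were lower in all 3. With only 2 N2 libraries, which cannot be split between the comparisons, a shared effect and a shift of the shared controls were not told apart.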
